A study of Mus musculus with 2 samples.

How the data were processed

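DNase-seq was done on 2 libraries of left cerebral cortex from B6CASTF1/J mice, per the labels, and each library had 5 deposited files. Per the deposited readme files these were 2 peak lists, a footprint list, a per-base cut rate table and a description, all on the mm10 build, each made from the alignments of its own library, so that peaks were called per library and not on pooled reads. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The signal of each peak (column 7 of the narrowPeak format) was deposited by the authors without a stated normalization. Within a library all signals were whole multiples of a smallest step (within 0.02 of a step), 0.00681 in library 1 and 0.00617 in library 2, as a count scaled by a factor per library would be, and no read counts were derived from them. The per-base tables deposited by the authors hold a false discovery rate, a q-value, per run of bases and list values under 0.05 only. The deposited footprint lists hold the q-value 0.01 in every line, read here as a threshold. Every peak of the longer list held a base with a false discovery rate under 0.05 and every peak of the shorter list one under 0.001. The longer list was used throughout, with 132054 and 139799 peaks, and the shorter one, with 79331 and 84096, as an alternative. The cross carries a CAST genome, and how the authors treated differences between the strains when placing reads is not given in the sources used here.

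The GENCODE M21 annotation and the matching mm10 genome were used for chromosomes 1 to 19, X and Y. Peaks counted as shared with an overlap of at least 1 base, and matched pairs were peaks that were each other's strongest overlapping peak. Chance overlap came from 20 random placements of the peaks on their own chromosomes, and that of footprints from 20 placements within the peaks. A peak was a promoter peak with its midpoint within 500 bases of an annotated start, then exon, intron or outside genes in this order; a gene had a promoter peak where any peak lay within 500 bases of any of its starts. A start of a neighbouring gene can lie in that window, so a promoter peak is not always the listed gene's own. The promoter signal of a gene was its strongest such peak, or 0. The 25 gene lists, with 294 entries, and the 20 consensus motifs were fixed before the data were examined. The list entry Ttr stands in both the ependymal and the liver list. Peaks over each gene and 10 kb on either side were turned into a percentile among the 200 protein-coding genes of nearest span, and list medians were set against 10000 random lists (permutation test, two-sided). Shared and unshared peaks near list genes were compared by Fisher's exact test. Both used Benjamini-Hochberg adjustment over lists. A list was called by percentile where both libraries passed 0.05, and by unshared peaks in each library separately. The test of unshared peaks was repeated with genes as units and without single genes, both added after the data were examined. There was no test per gene.

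Consensus matches on either strand were counted by the position of their middle, in footprints within peaks (3.05 and 3.58 Mb) and in the rest of the peaks (23.1 and 25.3 Mb). Each consensus was compared with 10 pooled versions with permuted letters, and a ratio was given where at least 50 matches were found. Named genes followed a rule fixed before the data were examined. They are the 2 members of each cell type, region and response list with the highest mean percentile, the highest and the lowest member of each control list, the 10 shared peaks of highest mean rank by signal, and the 5 strongest unshared peaks of each library. Some items that this rule takes are not reported here. Any other gene is said to be chosen after its values were seen. Alternatives were the overlap of at least 50% of both regions, the shorter list, the stronger part of the peaks by signal, equal peak numbers, promoter windows of 250 and 2000 bases, flanks of 0 and 50 kb, stricter false discovery rates of 0.005 and 0.001, another background for motifs and each library alone. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 searched for copies of the strongest peaks (identity of 90% or more over at least 50% of the peak).

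The percentile test, peak sharing, the motif search and both tests of unshared peaks by permutation were tested on simulated data, and the other steps were not. With peak counts simulated for the 21938 protein-coding genes, 100 of 100 lists raised 3-fold were called, 74 of 100 lists lowered to 1 in 3 were called, and 2 of 300 unchanged lists were called, so the test finds gains more readily than losses. Of 92652 library 1 peaks shifted by less than the width of the narrowest peak (21 bases) all were found as shared, and 2.57% of the 39402 moved at random. Such small shifts always leave an overlap, so finding all of the shifted peaks was fixed in advance. All 3980 planted motif sites were found. The test of unshared peaks within strata called 1 of 40 simulations without an effect and 40 of 40 with one. Peaks were simulated as independent there, so these rates do not cover unshared peaks that gather at single genes. The test with genes as units, which sets the share of unshared peaks of a list against 10000 random lists of genes with like peak counts, called 33 of 100 lists raised 2-fold and 2 of 400 unchanged ones, so it misses many changes of that size.

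Both libraries carry biological replicate numbers, and no label says that they came from separate animals. An SD over both therefore measures the spread between these samples, which may be technical. The tests set genes or peaks against one another and do not measure that spread. The files of the libraries hold different peaks and signals, so they were counted as 2 samples, which does not show that they came from separate animals. With 1 group there is no comparison between conditions. Sex, age and strain were the same in both libraries, and their effects were not analysed here.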

Results

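Chromatin accessibility was measured by DNase-seq, in which the enzyme DNase I cuts DNA where it is not covered by nucleosomes and the cut sites are sequenced. The tissue was the left cerebral cortex of aged female mice, 18 to 20 months old, of the B6CASTF1/J cross, the first-generation hybrid of the C57BL/6J and CAST strains. There was 1 group with 2 libraries, named library 1 and library 2 here after their biological replicate numbers. The labels give the libraries separate tissue samples and the same donor identifier, and do not say that they came from separate animals. The design therefore implies no comparison between conditions, and the values below describe each library and compare the pair as replicates, where a mean is followed by its SD over both (n = 2). The peak lists gave 132054 peaks in library 1 and 139799 in library 2, some of which overlap others of the same list. They covered 26.1 and 28.8 Mb, or 0.987% and 1.09% of the genome. The median peak was 200 bases wide in both, and the median signal was 0.640 in library 1 and 0.641 in library 2. The number of sequenced reads is not given in the sources used here, so the depth is unknown and intervals below cover the counting of regions only.

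Promoters of excitatory neuron, pan-neuronal and cortical layer genes were open in both libraries, and promoters of liver, muscle, skin and blood genes were mostly closed. All 12 genes of excitatory neurons, all 14 pan-neuronal genes and all 10 genes each of the upper and deep cortical layers had a peak within 500 bases of an annotated start in both libraries. None of the 12 liver genes did, although 1 of them, Apob, had a weak promoter peak of signal 0.265 in library 2. Among protein-coding genes in general, 13956 of 21938, or 63.6%, had a promoter peak in both libraries, 7161 had none in either, 198 had one in library 1 alone and 623 in library 2 alone. By library the share was 64.5% in library 1 (exact binomial 95% interval 63.9 to 65.2%) and 66.5% in library 2 (65.8 to 67.1%).

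Cell types of the cortex differed in how many of their genes had a promoter peak in both libraries. Among glial lists these were 11 of 12 astrocyte genes, 9 of 10 genes of oligodendrocyte precursors and 7 of 12 of mature oligodendrocytes. The counts were 11 of 14 for inhibitory neurons, 4 of 12 for microglia and 2 of 12 for endothelial cells (2 in library 1 and 4 in library 2). They were 4 of 12 (5 and 7 by library) for mural and leptomeningeal cells, which surround vessels and form the inner meninges. For ependymal and choroid plexus cells the count was 3 of 10. Of the endothelial genes the exceptions were Slc2a1, the glucose transporter of the blood-brain barrier, with a promoter signal of 3.31 ± 0.0659, and Kdr, a receptor for vascular endothelial growth factor. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had a promoter signal of 1.53 ± 0.0608, and Camk2a, a synaptic kinase, of 3.99 ± 0.102. Gad1, which makes the transmitter GABA, stood at 0.652 ± 0.0369, and neither Vip nor Aqp4, the water channel of astrocytes, had a promoter peak in either library. Apob, Kdr, Slc17a7, Camk2a, Gad1, Vip and Aqp4 were chosen after their values were seen.

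Of genes of neighbouring brain regions, 11 of 12 striatal and 8 of 10 hippocampal genes had a promoter peak in both libraries, against 3 of 12 of the cerebellum and hindbrain, where library 1 had 3 and library 2 had 7. Of response genes, all 12 immediate early genes, which neurons switch on within minutes of activity, and all 12 core clock genes had one, as did 9 of 12 genes of glial reactivity and ageing. All 14 housekeeping genes had one. The remaining control lists stood at 2 of 12 muscle and heart genes, 2 of 12 epidermis genes, 2 of 12 testis genes (2 in library 1 and 6 in library 2), 2 of 11 lymphoid genes and 1 of 10 erythroid genes. In a two-sided Fisher's exact test of each list against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 25 lists, 7 lists had more promoter peaks. By this exact test these were excitatory neurons (adjusted p = 0.012), pan-neuronal genes (0.0094), upper layers (0.029), deep layers (0.029), immediate early genes (0.012), clock genes (0.012) and housekeeping genes (0.0094). The same exact test found fewer for 8 lists: endothelial cells (0.0050), cerebellum and hindbrain (0.023), liver (0.00013), muscle and heart (0.0050), epidermis (0.0050), testis (0.0050), lymphoid (0.0094) and erythroid genes (0.0050). The other 10 did not pass, microglia and mural cells at 0.054 each, ependymal cells at 0.060, and astrocytes and striatal neurons at 0.084 each. This test was added after the data were examined, genes are not replicates, and the p-values describe these 2 libraries. With a window of 2000 bases around each start, 4 lists in place of 8 had fewer promoter peaks, those of endothelial cells, hindbrain, muscle and epidermis being lost, and 6 in place of 7 had more, with both layer lists lost and astrocytes added. The deep layer list also lost its call with 250 bases, in the stronger peaks and in the shorter lists. The calls of fewer promoter peaks for the hindbrain and testis lists were lost in library 2 alone, and that of the hindbrain also in the stronger peaks.

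Promoters of clock and immediate early genes were among the strongest of these lists. The median promoter signal was 6.71 ± 0.205 for the clock genes, 6.26 ± 0.0599 for the housekeeping genes and 5.33 ± 0.0355 for the immediate early genes. It was 2.86 ± 0.134 for pan-neuronal genes, 1.77 ± 0.103 for excitatory neurons, 1.81 ± 0.263 for upper layers and 1.28 ± 0.176 for deep layers. Among glia it was 1.59 ± 0.0441 for oligodendrocyte precursors, 1.08 ± 0.0918 for astrocytes and 0.423 ± 0.148 for oligodendrocytes, and for inhibitory neurons 0.803 ± 0.129. The 13956 protein-coding genes with a promoter peak in both libraries had a median of 3.30 ± 0.244. The list medians include genes without a promoter peak, so they are not like for like with this value. Nr1d1, a repressor of the circadian clock, reached 11 ± 0.202, and Dbp, a clock-controlled transcription factor, 8.65 ± 1.01. Arc, a regulator of synaptic strength induced by activity, reached 6.39 ± 0.628, and Egr3, an activity-induced zinc finger factor, 4.33 ± 0.0780. Signals are the authors' values per peak, and these differences in level were not tested.

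**Figure D1:**
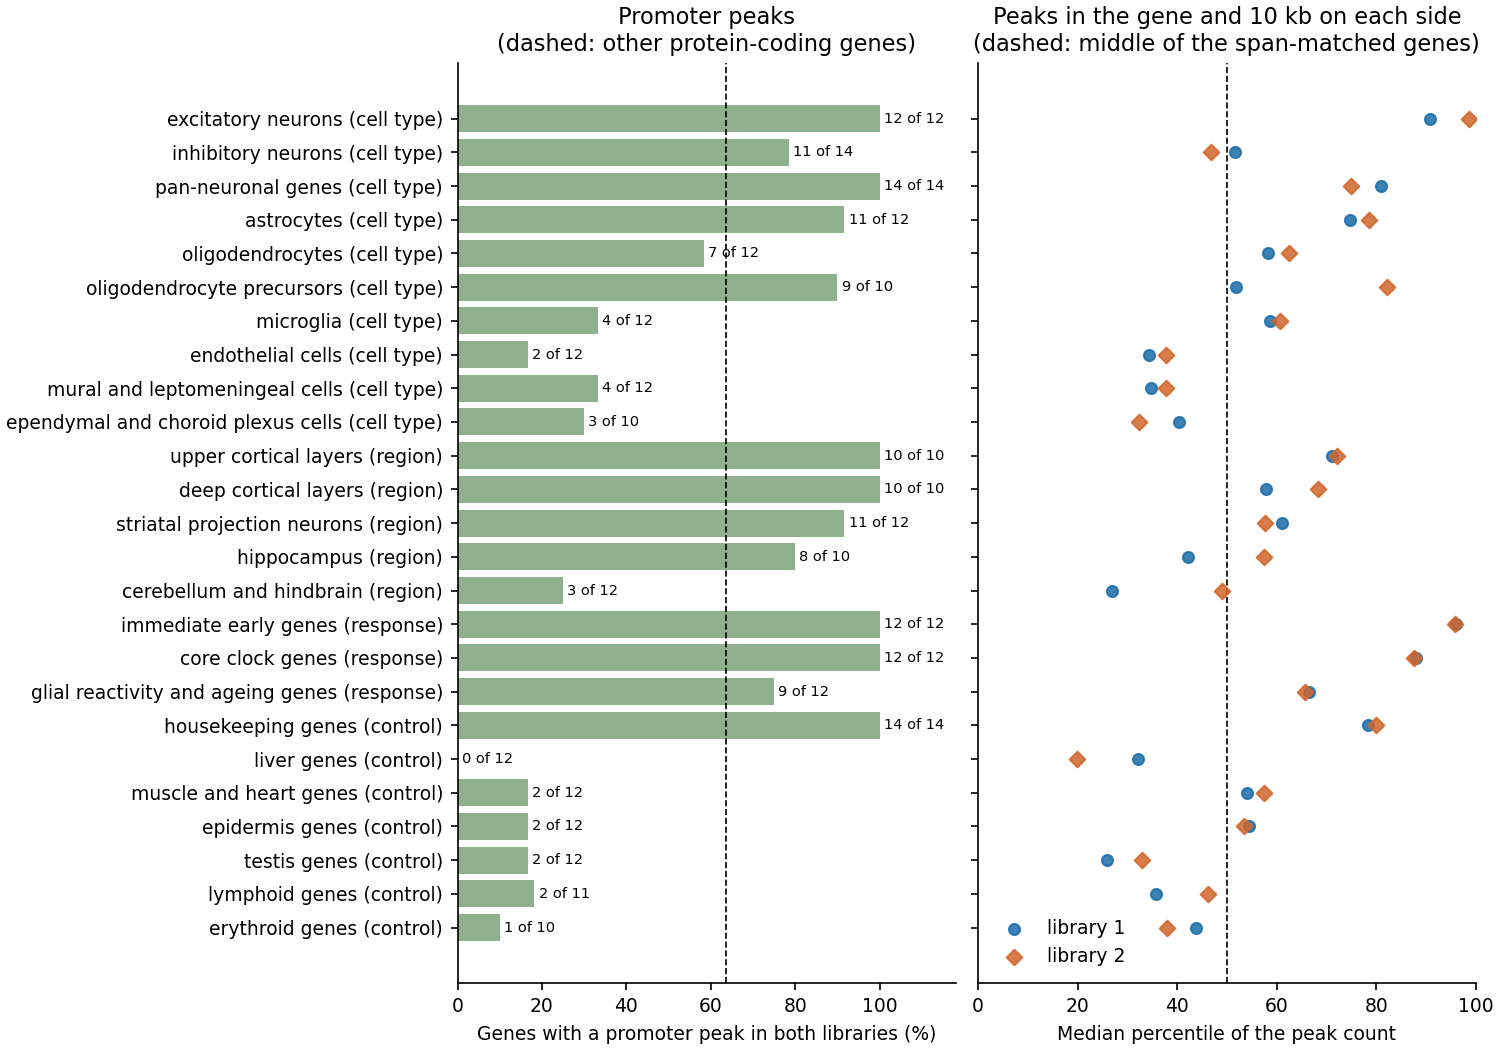
Left, the share of each list's genes with a promoter peak in both libraries (percent, count beside each bar); right, the median percentile of the peak count among genes of like span, 1 point per library. All bars of excitatory neurons, pan-neuronal genes, both groups of cortical layers, immediate early, clock and housekeeping genes reach 100%, and the excitatory, immediate early and clock lists lie furthest to the right.

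Excitatory neuron genes, immediate early genes and clock genes also held more peaks than other genes of their size. Peaks were counted over each gene and 10 kb on either side and turned into a percentile among the 200 protein-coding genes of nearest span. Overlapping peaks of a list were not merged, so counts are of listed peaks and not of separate regions. In library 2 at Tbr1, for instance, the peak at 61804621 to 61804740 lay within that at 61804101 to 61804880. The median percentile of the excitatory neuron genes was 90.8 in library 1 and 98.6 in library 2. It was 96.0 and 95.8 for immediate early genes and 87.9 and 87.5 for clock genes. Against 10000 random lists of the same size, a two-sided permutation test with Benjamini-Hochberg adjustment over the 25 lists gave adjusted p = 0.0025 in both libraries for the excitatory list (12 genes) and the immediate early list (12 genes). Both rest on a raw p of 0.0002, the smallest these permutations can give. For the clock list (12 genes) the adjusted permutation p was 0.0083 in library 1 and 0.012 in library 2. No list was lower in both libraries: at an unadjusted permutation p under 0.05 the liver list alone was lower in library 2 (median percentile 19.9, unadjusted p = 0.021, 12 genes) and none was in library 1. With a flank of 50 kb the excitatory list no longer passed, with median percentiles of 69.0 and 80.4 and adjusted permutation p of 0.41 and 0.094 (12 genes). Counting inside gene bodies alone, or in peaks above the median signal, 5 lists were higher in both libraries.

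Among excitatory neuron genes, Tbr1, a transcription factor of glutamatergic neurons (chromosome 2, 61802930 to 61814114), had 14 peaks in library 1 and 19 in library 2, a percentile of 99.5 ± 0.707. Nrn1, a neuronal growth factor, had 15 and 23 peaks (99.5 ± 0.707). Of the pan-neuronal genes, Rbfox3, which encodes the neuronal nuclear antigen NeuN (chromosome 11, 118489762 to 118911597), had 70 and 73 peaks, the top percentile of 100 in both libraries, and Celf4, an RNA-binding protein, had 45 and 47 (98.6 ± 0.177). The pan-neuronal list as a whole stood at 81.0 and 74.9, and passed in library 1 (adjusted permutation p = 0.040, 14 genes) but not in library 2 (0.11). Of the upper layer genes, the POU factors Pou3f2 (19 and 23 peaks) and Pou3f3 (15 and 11) reached percentiles of 100 and 98.0 ± 2.83. Of the deep layer genes, Bcl11b, a factor of corticospinal neurons, had 18 and 19 peaks and Nr4a2 had 7 in each library. The upper layer list stood at 71.0 and 72.1 and the deep layer list at 57.8 and 68.3, and neither passed. The inhibitory neuron list stood near the middle, at 51.6 and 46.8. Its highest members were Slc32a1, the vesicular transporter of GABA (3 and 7 peaks), and Npy, a neuropeptide (4 and 5).

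Single glial genes were rich in peaks although their lists did not pass. Mbp, which encodes myelin basic protein, had 21 and 25 peaks (percentile 98.9 ± 0.177), and Myrf, the regulator of myelin genes, had 9 in each library (92.0 ± 2.83). Sox8 had 14 and 12 peaks and Olig1 8 and 7 in the list of oligodendrocyte precursors, whose median was 51.9 in library 1 and 82.1 in library 2 (adjusted permutation p of 0.88 and 0.055, 10 genes). Of the astrocyte genes, Aldh1l1, a folate enzyme, had 19 and 22 peaks and Sox9 had 9 and 7, and the list stood at 74.6 and 78.5 (0.24 and 0.074, 12 genes, permutation test). The mature oligodendrocyte list stood at 58.3 and 62.4 and the microglia list at 58.8 and 60.6, with Aif1 (4 and 9 peaks) and Cx3cr1 (19 and 24) as the highest microglial genes. Endothelial genes stood at 34.4 and 37.8, where Slc2a1 (10 peaks in each library) and Pecam1 (10 and 11) were highest. Mural and leptomeningeal genes stood at 34.8 and 37.8, with Col1a1 (5 and 6) and Foxc1 (2 and 7). Ependymal and choroid plexus genes stood at 40.4 and 32.4, with Ccdc153 (5 and 4) and Kl (7 and 6).

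Genes of other brain regions gave mixed values. Ppp1r1b, which encodes the striatal dopamine signalling protein DARPP-32, had 11 and 18 peaks, while the striatal list stood at 61.0 and 57.6. The hippocampal list stood at 42.1 and 57.5, with Fibcd1 (9 and 10 peaks) and C1ql2 (7 and 4). The cerebellum and hindbrain list stood at 26.9 and 49.0, with Cbln1 (4 and 7) and En1 (2 and 4). The list of glial reactivity and ageing stood at 66.5 and 65.8, with Lcn2 (10 and 8 peaks, no promoter peak) and H2-D1 (4 in each). Of the controls, housekeeping genes stood at 78.3 and 79.9, from Gapdh (6 and 16 peaks) down to Pgk1 (2 in each). Ttn, the giant protein of muscle (chromosome 2, 76703980 to 76982547), had 4 peaks in each library, a percentile of 1.63 ± 0.177, and Acta1 had 5 and 8, with the muscle and heart list at 54.1 and 57.5. No peak was found in either library at Fga of the liver list, Dsg3 of the epidermis list, Ms4a1 of the lymphoid list or Gata1, the erythroid regulator. Their lists stood at 32.1 and 19.9, 54.5 and 53.5, 35.8 and 46.3, and 43.9 and 38.0. The highest members of the epidermis, lymphoid and erythroid lists were Sfn (5 and 4 peaks), Cd4 (12 and 10) and Epor (7 and 8). The testis list stood at 26.0 and 33.0, from Tnp2 (5 and 7) to Sycp1 (0 and 1).

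**Figure D2:**
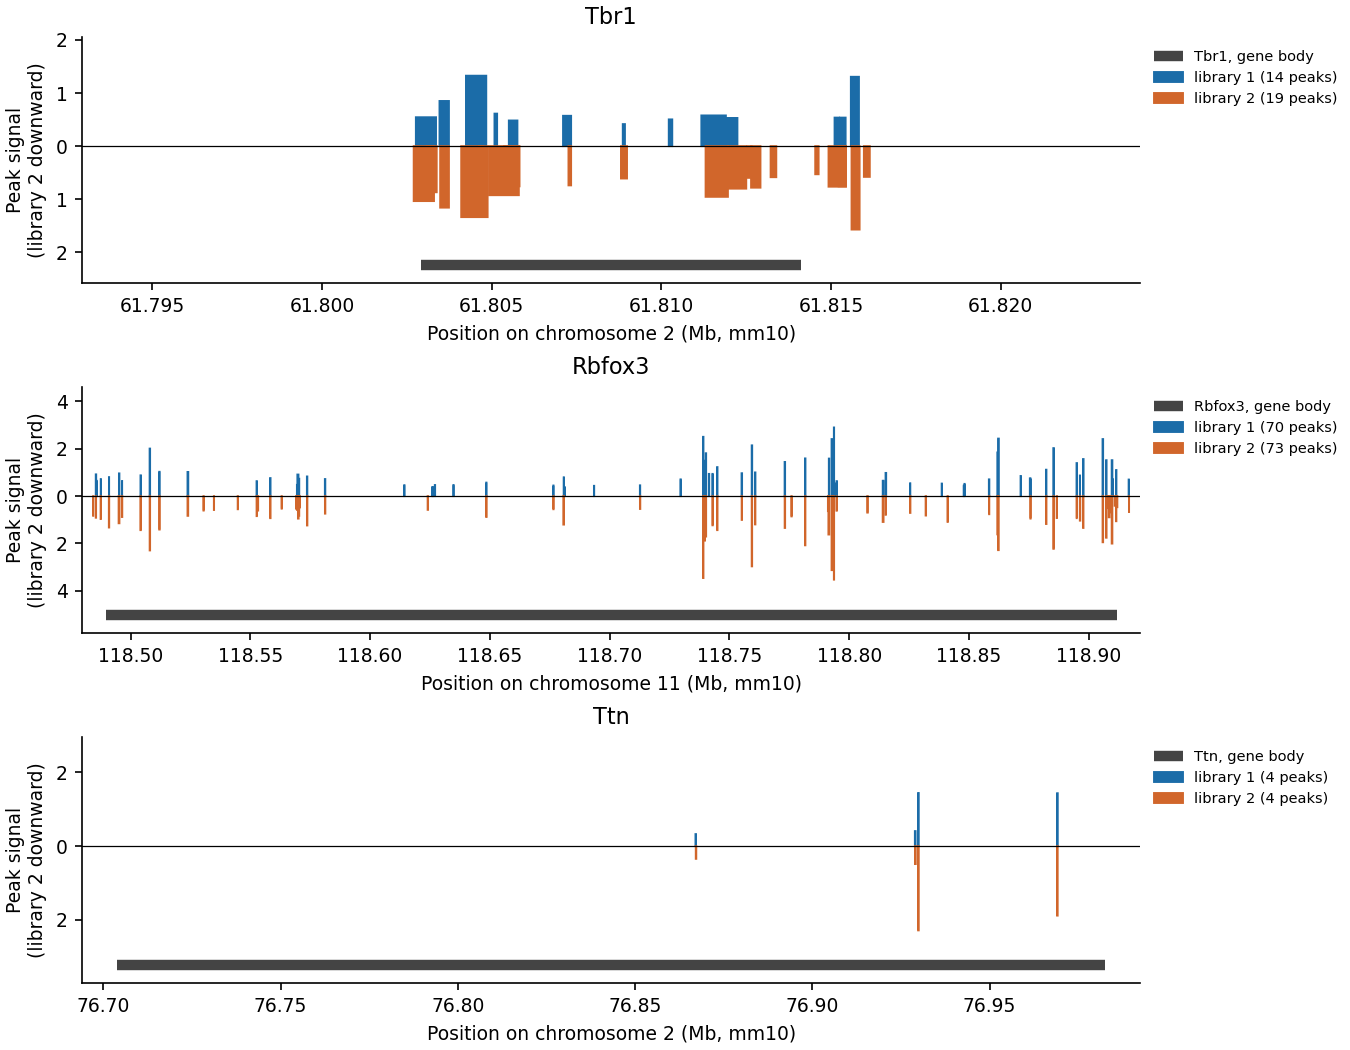
Called peaks at Tbr1, Rbfox3 and Ttn with 10 kb on each side (position in Mb, mm10), with bar height the authors' peak signal, upward for library 1 and downward for library 2, and bars drawn no narrower than a thin line. Tbr1 held 14 and 19 peaks and Rbfox3 70 and 73, against 4 in each library at Ttn.

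Peaks were concentrated at promoters. In library 1, 20.5% of peaks had their midpoint within 500 bases of an annotated start, against 3.40% of peaks placed at random on the same chromosomes, and in library 2 the values were 20.5% and 3.41%. Exons held 5.79% and 6.52% (3.88% and 3.89% at random), introns 40.1% and 40.3% (41.7% and 41.8%) and regions outside genes 33.6% and 32.7% (51% and 50.9%). Promoter peaks were stronger, with a median signal of 1.23 in library 1 and 1.31 in library 2 against 0.585 and 0.573 for other peaks. Chromosome 11 had the most peaks per Mb (72.0 and 78.1) and, leaving out Y, chromosome X the fewest (21.1 and 22.2).

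Both libraries called most of the same regions. Of the library 1 peaks 77.8% (exact binomial 95% interval 77.5 to 78.0%) overlapped a library 2 peak by at least 1 base, and of the library 2 peaks 73.2% (73.0 to 73.5%) overlapped one of library 1. Randomly placed peaks gave 2.30% ± 0.0416 and 2.17% ± 0.0365 (SD over 20 shuffles). Sharing rose with signal: in the weakest decile of each list 34.0% of library 1 peaks and 29.0% of library 2 peaks were shared, and in the strongest decile 99.6% and 99.5%. Unshared peaks had a median signal of 0.368 in library 1 and 0.376 in library 2, against 0.789 and 0.845 for shared ones. Over 99347 matched pairs the signals correlated with a Spearman rho of 0.917 and a Pearson r of 0.941 on the log2 scale. This correlation is across regions within a single pair of libraries, and regions are not independent replicates. The log2 ratio of library 2 over library 1 had a median of 0.09 and an SD of 0.40, and 1.59% of pairs differed by more than 2-fold.

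**Figure D3:**
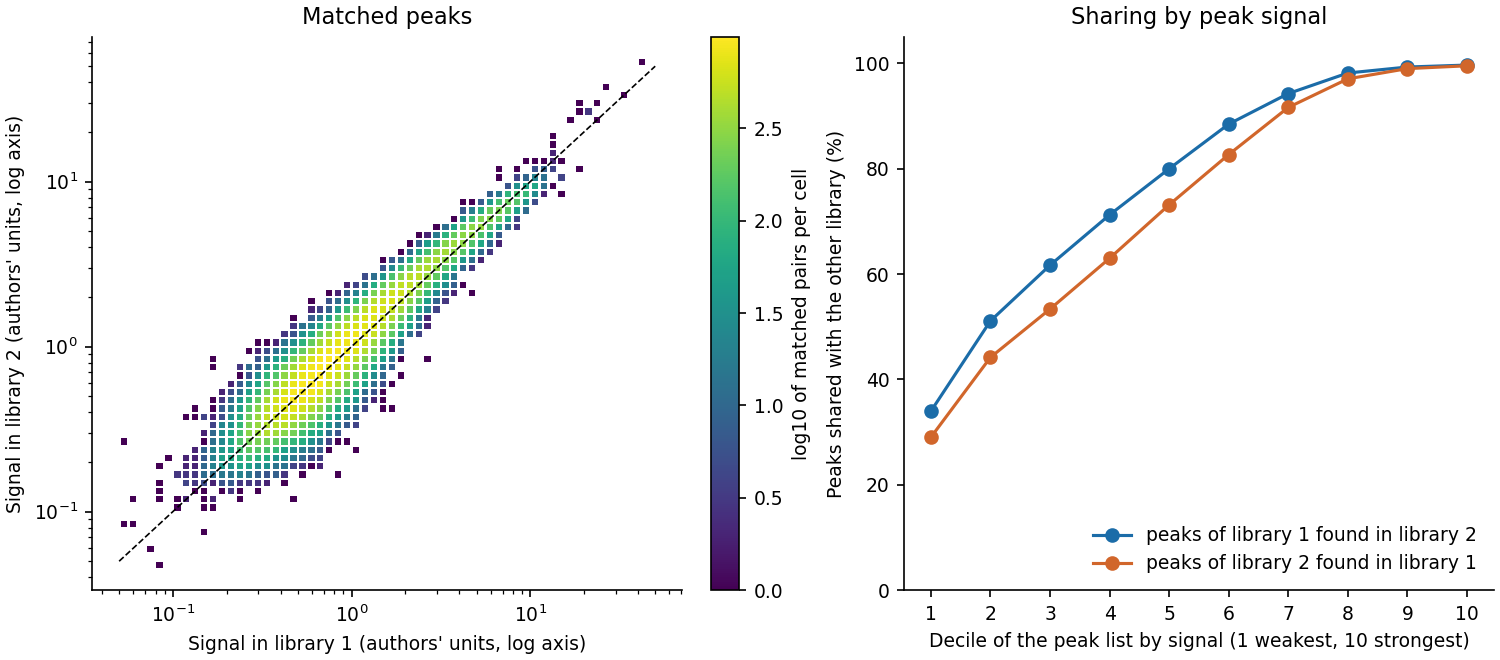
Left, signal of matched peaks in library 1 and library 2 (authors' units, log axes, colour the log10 number of pairs, dashed line equality); right, the percent of peaks shared with the other library in each decile of the list by signal. Sharing runs from 34.0% and 29.0% in the weakest decile to 99.6% and 99.5% in the strongest.

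Of the 10 strongest shared peaks, 6 lay more than 500 bases from an annotated start. The first in both libraries lay on chromosome 17, 39846781 to 39846920, in an exon of CT010467.1 and 107 bases from the start of the noncoding gene Gm42418, with a signal of 47.9 ± 4.68. The next lay in Gm21887 on chromosome X (170009841 to 170010180 in library 1, 33.9 ± 0.747) and in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461901 to 123462120 in library 1, 32.9 ± 8.72). Further ones lay in Il31ra (24.2 ± 6.74), in an exon shared by Gm15564 and Kpna1 (24.3 ± 3.56), in an exon of Cers5 (23.5 ± 3.29) and 10 bases from a start of Trpm8 (23.8 ± 1.23). The last 3 of the 10 lay outside genes on chromosome 3 (26.8 ± 3.34), chromosome 6 (23.8 ± 3.97) and chromosome X (23.3 ± 6.74). Of these 10 peaks, 8 had a further copy of their sequence elsewhere in the assembly, all but those at Trpm8 and Cers5.

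The strongest peaks found in only a single library lay beside a peak of the other. In library 1 they were in Mid1 on chromosome X (signal 13.5), beside Rab40c (10.3), Ubfd1 (6.55), Pcnx3 (5.89) and Ngdn (5.82). In library 2 they were beside Evi5l (5.82), Ubfd1 (5.46), Mynn (4.57), Nol7 (4.32) and Stx4a (4.24). All 10 lay within 60 bases of a peak of the other library, and for Pcnx3 and Stx4a the peaks touched with 0 bases between them.

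Library 2 held additional peaks around most excitatory neuron genes and around single genes of other lists. Of its 264 peaks near the excitatory list 126, or 47.7%, had no counterpart in library 1, against 25.8% near other protein-coding genes. The share was 69.2% (27 of 39) near the cerebellum and hindbrain list, 39.5% (66 of 167) near the deep layer list and 37.9% (44 of 116) near the precursor list. Peak counts were higher in library 2 at 11 of 12 excitatory neuron genes, 7 of 12 hindbrain genes, 7 of 10 deep layer genes and 5 of 10 precursor genes. Library 2 had more peaks in all (139799 against 132054), and no such count over all protein-coding genes is given here for comparison. Genes picked after their values were seen were Sox5, a factor of deep layer neurons (50 peaks in library 1 and 71 in library 2), Fezf2, a factor of subcerebral projection neurons (1 and 19), Neurod2, a neuronal bHLH factor (2 and 19), Camk2a (13 and 25) and En2, a midbrain and hindbrain homeobox gene (0 and 12), besides Zic1 (0 and 4) and the overlapping Zic4 (0 and 5). Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over the lists, gave adjusted p = 6.4e-13 for the excitatory list, 2.2e-07 for the hindbrain list, 0.0011 for the deep layers and 0.026 for the precursors. No list passed among the peaks of library 1. This test counts neighbouring peaks as independent and compares these libraries, not conditions. With genes as units, against random lists of genes with like peak counts, the excitatory list (adjusted permutation p = 0.015, 12 genes) and the hindbrain list (0.0050, 11 genes with peaks) passed, and the deep layers (0.37) and precursors (0.44) did not. There a peak near 2 genes of a list counts for each, as at Zic1 and Zic4, which are not separate units. The hindbrain share tested was therefore 72.1%. Genes were left out in the exact test only. Without Fezf2 the deep layer share was 32.4% (exact test, adjusted p = 0.37). Without Lhfpl3 the precursor share was 35.1% (0.27), and that list also lost its call without Olig2, Vcan or Tmem132b. The genes left out were likewise picked after their values were seen. The hindbrain share was 55.6% without En2 (0.011) and 45.5% without En2 and Zic4 (0.27), and the excitatory share was 40.5% without Neurod2, Grin2a and Camk2a (0.00070). In the signal of matched peaks none of these 4 lists passed. That signal covers only peaks called in both libraries, so it cannot show a difference at the unshared peaks. Only 6 of the 12 hindbrain genes had matched peaks. The median log2 ratio per gene was centred on the median of all matched pairs. It was 0.10 for the excitatory list (10 of 12 genes above 0) and 0.17 for the hindbrain list (5 of 6). For the deep layers it was -0.05 (3 of 10) and for the precursors -0.11 (2 of 9). Against random lists the adjusted permutation p was 0.37, 0.34, 0.44 and 0.33. Of the 25 lists only the liver list passed this test, at -0.30 over 7 genes (adjusted permutation p = 0.020). The test of signal was added after the data were examined.

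Footprints are short stretches inside accessible regions that were cut less than their surroundings, as where a protein covers the DNA. There were 271439 in library 1 and 323715 in library 2, with a median width of 9 bases in both. Of these 91.5% and 89.9% lay in peaks, and 76.1% and 78.9% of peaks held at least 1. Of the library 1 footprints 52.4% overlapped one of library 2, and of the library 2 footprints 43.4% overlapped one of library 1, against 18.7% and 16.5% when footprints were placed at random within the peaks. These placements did not keep the number of footprints per peak, so they do not allow for footprints that gather in the same peaks. Among footprints in peaks called in both libraries the shares were 60.3% and 53.7%, for which no random value was drawn.

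Recognition sequences of NRF1, a factor of many promoters, and of the insulator protein CTCF were the most concentrated in footprints. Matches to the NRF1 consensus were 77.6 ± 18.5 times as dense in footprints as in the rest of the peaks, and CTCF matches 50.9 ± 10.8 times, with 87.2% ± 2.93 of the CTCF matches in peaks lying in a footprint. The ratio was 17.1 ± 3.55 for CREB, which binds the cAMP response element, 15.7 ± 2.24 for the EGR family, 11.6 ± 1.89 for RFX, 9.86 ± 1.11 for NFI, 9.83 ± 0.524 for SP/KLF and 7.89 ± 0.583 for YY1. It was 4.11 ± 0.431 for ETS, 3.31 ± 0.217 for the E-box of NEUROD and related neuronal factors, and 1.32 ± 0.144 for AP-1, the site of FOS and JUN proteins. Versions of each consensus with permuted letters gave 1.82 for NRF1, 1.38 for CTCF, 0.630 for CREB, 2.66 for EGR, 0.946 for the E-box and 0.704 for AP-1. The permuted GC box of SP/KLF reached 6.83, close to the value of the true one. MEF2 stood at 0.750 in library 1 and 1.37 in library 2, both above its permuted versions (0.407 and 0.483) but on opposite sides of 1.

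Of the 20 motifs, 12 were denser than their permuted versions in both libraries by intervals that did not overlap, 6 were not, and the others gave no comparison, among them REST, whose own ratio was 1.97 in library 1 and 2.24 in library 2 but whose permuted versions had too few matches. The 6 were SOX (0.588), SPI1 of myeloid cells (0.598), POU (0.552), LHX (0.424), HNF4A of liver (0.913) and GATA of blood cells (0.282). Their permuted versions were low as well, at 0.533, 0.591, 0.430, 0.695, 0.649 and 0.395 in the same order. A low ratio by itself therefore does not show that a motif was depleted from footprints. Outside promoters CTCF matches were 4.0 ± 0.0289 times as dense per base of peak as in promoter peaks, AP-1 3.50 ± 0.276, NFI 3.30 ± 0.631, the neuronal E-box 3.23 ± 0.167 and MEF2 2.42 ± 0.264 times. At promoters the order was the other way for YY1 (0.0381 ± 0.00122), ETS (0.0802 ± 0.00642), SP/KLF (0.0981 ± 0.00446) and NRF1 (0.112 ± 0.0162). Intervals are 95% counting intervals, and the rule for calling a motif was set after the match counts were seen. A match shows the sequence only, since several proteins bind most of these motifs.

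**Figure D4:**
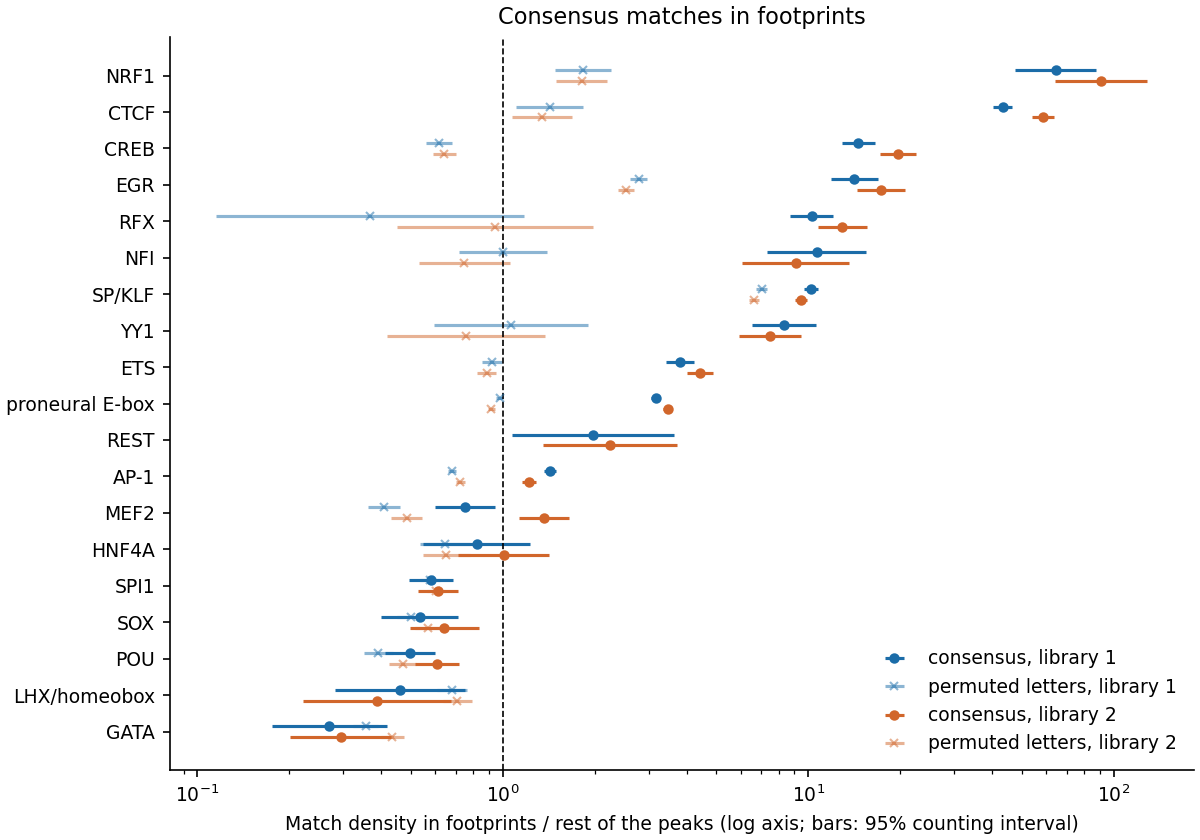
Density of consensus matches in footprints divided by that in the rest of the peaks (log axis), per library, with 95% counting intervals, as points for the consensus and crosses for its permuted versions. NRF1 and CTCF lie furthest to the right at 77.6 and 50.9 on average, and GATA furthest to the left at 0.282.

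The per-base files listed 39.96 Mb in library 1 and 45.3 Mb in library 2 with a false discovery rate under 0.05 for the local cut rate. Of all bases listed in either library 63.4% were listed in both, which is 33.1 Mb. Library 2 had more listed bases, more peaks and more footprints than library 1.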

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

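The alternatives were fixed before the data were examined, with these exceptions: the stronger part of the peaks for sharing, the shorter list for signal, annotation, promoters and lists, the false discovery rate of 0.001 and all settings of the promoter test of gene lists were chosen after seeing the data. No paired analysis was possible because there is only 1 group. Selecting the stronger footprints could not be run, since every footprint carries the same value. The number of reads is unknown, so no limit from depth can be given.

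Sharing of library 1 and library 2 peaks moved from 77.8% and 73.2% to 64.1% and 60.6% with at least 50% of both peaks overlapping, 81.8% and 77.1% in the shorter lists, 76.4% and 76.1% with equal peak numbers and 87.1% and 82.4% in the stronger part of the peaks. The signal correlation of 0.917 became 0.925 with 50% overlap, 0.894 in the stronger peaks and 0.924 in the shorter lists. Footprint sharing of 52.4% and 43.4% fell to 38.2% and 32.0% with 50% overlap. The shared part of listed bases, 63.4%, became 65.1% at a false discovery rate under 0.005 and 65.2% under 0.001.

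The promoter share of peaks, 20.5%, became 30.3% in the stronger peaks, 15.5% and 33.5% with windows of 250 and 2000 bases and 27.4% in the shorter lists. In the windows of 250 and 2000 bases and the shorter lists, exons moved from 6.15% to 7.65%, 3.53% and 5.54%. For the stronger peaks and then those 3 settings, introns moved from 40.2% to 37.2%, 42.8%, 32.6% and 36.1%, and regions outside genes from 33.2% to 26.5%, 34.0%, 30.3% and 31%. Single libraries ranged from 20.5% to 20.5% for promoters, 5.79% to 6.52% for exons, 40.1% to 40.3% for introns and 32.7% to 33.6% outside genes. Genes with a promoter peak moved from 65.5% to 64.0% and 69.9% with windows of 250 and 2000 bases, 59.5% in the stronger peaks and 61.2% in the shorter lists, and single libraries gave 64.5% to 66.5%. These shifts follow from how each setting selects or widens regions.

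Of the 25 gene lists 3 were called by peak count. Gene bodies alone gave 5 (pan-neuronal genes and astrocytes added), as did the stronger peaks (pan-neuronal and housekeeping genes added), and both called the liver list lower. A flank of 50 kb gave 2, leaving out promoter peaks 3, the shorter lists 4 and single libraries 3 to 4. The cause of the loss of the excitatory list at 50 kb was not tested. The promoter test gave 7 lists with more peaks, 6 under the windows of 250 and 2000 bases, the stronger peaks and the shorter lists (deep layers lost in each, and with 2000 bases upper layers lost and astrocytes added), and 7 to 8 in single libraries. It gave 8 lists with fewer, and again 8 with the window of 250 bases, 4 with 2000 bases, 9 in the stronger peaks (7 of the first 8 among them), 10 in the shorter lists (all 8) and 6 to 8 in single libraries, with hindbrain and testis lost without library 1. The 4 lists with more unshared peaks in library 2 also passed with equal peak numbers, and 2 of them (excitatory neurons and hindbrain) with genes as units, a setting chosen after seeing the data. With 50% overlap 6 passed, adding library 1 peaks of the excitatory list and library 2 peaks of the striatal list.

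Of the 20 motifs 12 were above their permuted versions, as with shared footprints and in each single library, and 13 against flanks of 20 to 200 bases, where REST gave no value. The MEF2 ratio reversed, from 1.06 to 0.797 in shared footprints and 0.750 without library 2, so that it ranged from 0.750 to 1.37 between libraries, and the cause was not tested.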

Other observations

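All tests in this part, the gene families included, were chosen after the patterns they address had been seen, and with only 1 group no biological explanation was tested beyond higher accessibility in library 2, whatever its source.

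Large gene families used outside the cortex had few promoter peaks. Of 1135 olfactory receptor genes 23, or 2.03%, had a promoter peak in both libraries, as did 5 of 329 vomeronasal receptor genes, 4 of 66 defensins, 6 of 53 keratins, 8 of 33 interleukins and 23 of 100 cytochrome P450 genes. Of the 39 Hox genes, which pattern the body behind the forebrain, 4 had one: Hoxa7, Hoxa10, Hoxc5 and Hoxd1. The clustered protocadherins, adhesion genes of which single neurons use a few, stood at 17 of 57 in both libraries and at 31 of 57 in at least 1. Families used in all cells were mostly open, with 76 of 79 ribosomal protein genes, 35 of 36 subunits of mitochondrial complex I and 37 of 39 proteasome subunits. Most histone genes (58 of 67) and Zfp genes (341 of 394) also had a promoter peak in both libraries. Of neuronal families, 36 of 40 voltage-gated potassium channel genes, 16 of 18 ionotropic glutamate receptor genes and 14 of 19 GABA-A receptor genes had one. In Fisher's exact test against other protein-coding genes, Benjamini-Hochberg adjusted over the 16 families, all but the GABA-A receptors (adjusted p = 0.48) passed, the glutamate receptors with the highest adjusted p among them (0.028).

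Peaks were also listed on chromosome Y, 50 in library 1 and 51 in library 2, although the mice were female. Of these 26 and 22 lay in a single segment of 50 kb, picked after the peaks were seen, and the median signals were 0.395 and 0.296, with highest values of 5.0 and 7.46.

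Of windows of 50 kb across the genome, 98 held at least 10 peaks more in library 2 and 6 at least 10 more in library 1, and 6 of the 98 overlapped the excitatory neuron, deep layer, precursor and hindbrain genes near which library 2 had additional peaks, with 131 peaks in library 2 and 37 in library 1. Weaker peaks alone would leave no excess at equal signal. Within signal deciles 263 peaks were unshared where 183.1 were expected, a ratio of 1.44. With genes resampled, which was added after the ratio was seen, its interval was 1.22 to 1.77. With GC and CpG content added to the strata the ratio was 1.40 (1.21 to 1.66). Both ratios lay above the bound of 1.2 set beforehand, so an excess remained at equal signal and base content. The 4 lists were picked by their unshared peaks in these same libraries, which can raise the ratio. Resampling genes does not allow for that choice, so neither explanation is excluded. Higher accessibility in library 2 could raise the peaks both libraries called. In these 6 windows their median log2 ratio, centred on that of all matched pairs, was -0.020, under the 0.1 set beforehand (35 peaks). The bootstrap interval was -0.15 to 0.08, a criterion added after the value was seen. This cannot decide the question, since the windows were chosen by peak counts and peaks called in library 2 alone are left out. The library 1 peaks there were strong, with a median signal of 1.62 against 0.640 for all its peaks. Over all 304 matched peaks near these genes the median ratio was 0.030 (-0.03 to 0.11). That interval reaches the bound of 0.1 and leaves higher accessibility open for the lists as a whole. A calling threshold that differs locally may be the cause and stays open: in the 4 of these windows with at least 5 peaks of library 1, 7.94% (5 of 63, Wilson interval 3.44 to 17.3%) of the unshared peaks exceeded 1.5 times the lowest library 1 signal of their window, under the 10% set beforehand, but the interval, applied after the value was seen, includes both 10% and the 14.7% of windows in general. A first test of this explanation, the share of library 1 peaks in the 6 windows below its median signal (8.11%), was set aside because the windows were chosen by their peak counts. The 4 windows of the test above were chosen in the same way. Their lowest library 1 signal had a median of 0.749, against 0.415 in all windows with at least 5 library 1 peaks. A higher lowest signal leaves fewer unshared peaks above 1.5 times it, so this test cannot decide the question either.

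Peaks with an AP-1 match outside promoters were weaker in library 2. Of 8695 such matched pairs 68.6% had the lower centred signal in library 2, against 50.01% of pairs without a match. A bias of weak peaks would vanish among strong ones, where the difference of the medians was still -0.16, and within strata of signal and GC content the difference of the means was -0.17 against -0.19 without strata, beyond the range of permuted matches, so neither explanation accounts for it. The shift was not particular to AP-1: of 17 motifs 13 lay beyond their permuted range within strata, 11 weaker and 2 stronger in library 2, of which 7 (RFX at -0.28 among them) and 1 (CTCF, 0.13) had the same sign without strata and stayed beyond it in the stronger part of the peaks, while SP/KLF and EGR were stronger in library 2 without strata. Its cause stays open.

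Of the 10 strongest shared peaks 6 lay over 500 bases from an annotated start, against 15 of the 100 strongest and 79.5% of 200 shared peaks drawn at random, so their place was unusual among strong peaks and not among peaks in general. Sequence present in further copies (repeats, ribosomal or mitochondrial copies) may account for those with a copy: 8 had a further copy of at least 90% identity in the assembly, against 7.5% of the random peaks, and none matched the mitochondrial genome. Among the 10, copies were about as common near a start as away from one, but among the 100 strongest, with a copy 10 lay away from starts and 10 at one, and without a copy 5 and 75, a difference of 43.75 percentage points (Fisher's exact test, p = 1.9e-05), and without the first 10 these were 5 and 7 with a copy and 4 and 74 without (exact p = 0.0017). Among the random peaks no such association was found, with 11 and 4 against 148 and 37 (exact p = 0.51), and the peak at Cers5 lay away from a start without a further copy, and its cause was not tested.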
